A study of Pseudomonas aeruginosa PA14 with 46 samples.

How the data were processed

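RNA was measured in 46 libraries of Pseudomonas aeruginosa PA14. Per the labels' protocols, 50 mL of LB were started from an overnight culture at an optical density (OD600) of 0.05 and shaken at 180 rpm and 37 °C, with samples every hour up to 10 h and the 2 runs made on different days. Cells were opened with lysozyme, RNA was purified on columns, treated with DNase and fragmented, barcodes were ligated, ribosomal RNA was removed with a bacterial depletion kit, and cDNA was read as pairs of 50 bases on an Illumina NovaSeq instrument. The molecule field of the labels reads polyA RNA, which differs from the depletion protocol. The protocol was followed here.

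The authors deposited 1 count file per library. Per the file headers these hold raw counts of read pairs for each of 6026 features, made with featureCounts 2.0.0 on the PA14 chromosome, with the strand taken into account and with pairs that map to several places or overlap several features counted in full for each. Near-identical genes therefore share counts. Per the submitters' processing notes, reads were aligned with Bowtie2 and handled with SAMtools, whose versions are not given in the sources used here. Values were checked to be whole numbers with the same features in every file, and the count files gave the positions used.

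Gene symbols were not in the count files. They were taken from an annotation table of another PA14 assembly by matching features on their exact lengths and their start-to-start spacing to at least 2 neighbours within a window of 4, where the pattern was unique in both annotations. This paired 5477 of 6026 features (90.9%), of which 1916 had a symbol and 1689 a symbol unique to 1 locus. As a control, the mirrored annotation gave 0 matches. Of 18 locus tags whose symbols were written down beforehand 17 received a symbol, all 17 the right one. Features left unpaired keep their locus tag and stay outside the gene lists.

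Each library was assigned to a time point, run and replicate from its labels, and each replicate of a run was taken as 1 culture sampled over time, which the labels do not state in full. Hours, comparisons (2 h against 1 h, 6 h against 2 h, 10 h against 6 h, each single hourly step and any time point), gene lists, panel, tests and 20 of the alternative settings were fixed before the data were examined. The other 4 settings were added after seeing the data and leave out the 1 h library of run B replicate 2, the 10 h library of run A replicate 3, the genes opposite dnaA, or tadD from the type II secretion list.

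Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr with the time points as groups were kept (6012), TMM factors ranged from 0.763 to 1.38, and a negative binomial quasi-likelihood model with robust settings was fitted to all 46 libraries with 1 coefficient per time point and a run term, leaving 35 residual degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, per comparison, and a 2-fold change is an estimated log2 change of at least 1 among them. The standard error of a log2 change is its absolute value divided by the square root of the F statistic. A difference between runs was tested in a second model with a mean for each run at each time point, as the contrast of the 2 runs' changes. Run A has 1 library at each hour from 7 h on, so its spread there was taken from the other groups. Principal components were computed on log2 CPM with a prior count of 2.

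Of 33 gene lists written from general knowledge of the species, 32 had at least 4 tested members with a symbol unique to 1 locus and were tested with camera of limma 3.58.1 on log2 CPM, with the correlation between genes estimated from the data, and adjusted over the lists of a comparison. The polyhydroxyalkanoate list had 2 members and was not tested. A list is described where camera called it or where at least 50% of its tested members were called in 1 direction with a 2-fold change. Beside each count, the count adjusted over that list's genes alone is given. Genes are named by a fixed rule: the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 10 CPM and the same direction in every culture sampled at both hours (rRNA and tRNA genes aside), up to 3 called members of each described list with the largest change and 1 of opposite direction, and a panel of 20 genes, of which 18 were found. The rule named 42, 95 and 46 results in the 3 comparisons, 183 in all.

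For the chromosome position analysis, each gene's log2 CPM relative to its mean over libraries was regressed on the shorter way round the chromosome to dnaA in each library, and the slopes of 10 h and 2 h libraries were compared by an exact permutation of labels. The chromosome length was taken as the end of the last feature, position 6537456.

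Depth was 3938555 to 29189118 counts per library. The common biological coefficient of variation was 19.8%. The chi-square per degree of freedom between libraries of a time point, over genes with at least 20 counts, had a minimum of 7.99 and a median of 21.8. It was 200.5 to 289.1 for pairs with the 7 h library of run B replicate 1, the deepest of all. Pairs with the 8 h library of that replicate gave 84.33 to 144. The other pairs gave 19.48 to 51.38 at 7 h and 7.99 to 30.54 at 8 h. Whether samples of a culture share more than their time point was checked by correlating residuals of paired libraries. Only pairs of the main comparisons were used (2 h against 1 h, 6 h against 2 h, 10 h against 6 h). The correlations were -0.232 to 0.08 over these 14 pairs. The run term was therefore used, and the culture was tried as a block in an alternative. Pairs of the hourly steps after 2 h were not checked. Run B replicate 1 stood out at both 7 and 8 h, so the check does not show that samples of a culture are unrelated at those steps.

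The steps were tested on simulated data with the real depths and dispersions and 3 sizes of change, planted in genes of at least 5 CPM. At log2 changes of 0.5, 1 and 2, 52.2, 88.1 and 100% of the changed genes were recovered for 2 h against 1 h, 47.8, 89.6 and 100% for 6 h against 2 h, and 40.3, 86.6 and 100% for 10 h against 6 h. Unchanged genes were called in 0.17, 0.1 and 0.21% of cases. A planted change in the flagellum list was called in all 3 comparisons with 0 other lists of 32. Genes were drawn independently there, around means that were flat over time. The list test was therefore not tried on correlated lists or where most genes change. A planted run difference of log2 2 in 200 genes was recovered in 85%, with 0.22% of other genes called, and a planted slope difference of 0.5 per Mb was returned as 0.498.

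Alternatives tried were median-of-ratios (RLE) factors, library size alone, no low-count filter, at least 10 counts in every library, DESeq2 1.42.0, no run term, culture as a block, each run alone, only the libraries compared, leaving out each culture, camera with a preset correlation of 0.01, the directional fry test, and for the position analysis the upper 50% of genes by expression, medians in 20 bins and leaving out rRNA, tRNA and ribosomal protein genes. Other splits of the samples were counted, up to 100 per comparison. Matching and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Sequence reads were not used here.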

Results

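The transcriptome of Pseudomonas aeruginosa PA14, a virulent reference strain of this opportunistic pathogen, was followed through batch growth in LB, a rich medium of peptides and yeast extract. RNA was sampled every hour from 1 to 10 h after dilution of an overnight culture, which gave 46 sequencing libraries from 5 replicate series, each taken here as 1 culture, in 2 runs on separate days. Run A supplied replicates 2 and 3 (16 libraries) and run B replicates 1 to 3 (30 libraries). Each of the time points from 1 to 6 h was represented by 5 libraries and each from 7 to 10 h by 4, because replicate 2 of run A was analysed here only to 6 h. Total counts per library ranged from 3938555 to 29189118, with a median of 7928171. Libraries of the same time point differed by more than sampling noise, with a chi-square of at least 7.99 per degree of freedom, so none was treated as a duplicate. CPM is a count scaled to the TMM-adjusted library size, given with its SD over n cultures, and log2 changes carry the standard error (SE) of the edgeR fit. Positions are those of the PA14 chromosome as the count files give them.

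Expression changed at nearly every gene over the 10 h. Of 6012 genes tested, 5728 (95.3%) differed between time points (edgeR quasi-likelihood F test, adjusted p under 0.05). The first principal component held 68.3% of the variance and parted the early from the late samples, with mean scores of -107.6 ± 8.74 at 1 h, -64.4 ± 2.43 at 3 h, 22.2 ± 3.70 at 4 h and 48.2 ± 1.23 at 5 h (SD, n = 5). Among the called genes, 1340 reached their highest mean at 1 h, 778 at 2 h and between 235 (6 h) and 691 (4 h) at each later hour. By gene list, the highest mean came at 1 h for 49 of 52 ribosomal protein genes. It came at 2 h for all 5 ATP synthase genes and 36 of 38 type III secretion genes. Maxima came at 4 h for 11 of 20 denitrification genes, at 9 h for 8 of 14 pyochelin and haem uptake genes and at 10 h for 13 of 17 pyoverdine genes. These hours were not tested against the hours beside them. Between 1 and 2 h, 5 of the 52 ribosomal protein genes were called lower and 0 of the 5 ATP synthase genes were called. Of the 38 type III secretion genes, 23 were called higher. From 8 to 10 h the pyochelin list stood at 2.19, 2.33 and 2.30 and the pyoverdine list at 2.34, 2.39 and 2.57 (log2 relative to all libraries). ssrA, the gene of transfer-messenger RNA, took 9.37 ± 0.640% of the counts at 3 h (n = 5) and 21.7 ± 1.08% at 8 h (n = 4). Among the libraries, 2 stood apart from their own time point on the first component. The 1 h library of run B replicate 2 scored -92.3 against -113.8 to -109.5 in the other 1 h libraries, and the 10 h library of run A replicate 3 scored 31.4 against 48.5 to 51.6. By another measure run B replicate 1 differed at 7 and 8 h. Its 10 most counted features took 53.07% of the counts at 7 h (others 39.73 to 44.82%) and 51.29% at 8 h (others 42.81 to 45.18%).

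**Figure D1:**
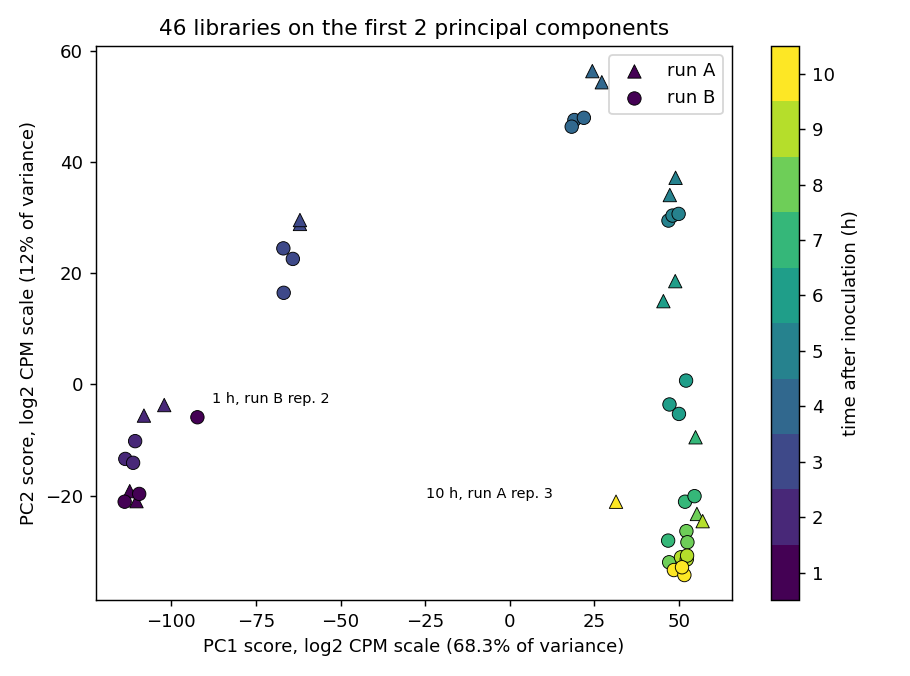
Scores of the 46 libraries on the first principal component (x axis, 68.3% of the variance) and the second (y axis, 12% of the variance) of log2 CPM; colour gives the hour, triangles run A and circles run B. The 1 to 3 h libraries lie at scores of -62 or below on the x axis and the 4 to 10 h libraries at 18.3 or above, and the 1 h library of run B replicate 2 (-92.3) and the 10 h library of run A replicate 3 (31.4) lie apart from their groups.

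The comparison of 2 h with 1 h covered the hours just after dilution into fresh medium. Transcripts of fpvA, feoA and tonB1, which serve the uptake of iron, rose, and that of bfrB, which encodes the iron-storage protein bacterioferritin, fell. The receptor gene for ferric pyoverdine, fpvA (PA14_33680, positions 2986159 to 2988606), went from 10.7 ± 9.17 to 58.2 ± 12.6 CPM (n = 5), a log2 change of 2.41 (SE 0.288, adjusted p = 4.23e-08). The pyoverdine list as a whole did not follow fpvA, its largest rise. Of its 17 genes 6 rose and 1 fell (6 and 2 adjusted over the list alone; median -0.23; limma camera, adjusted p = 0.689 with an estimated correlation). The bfrB transcript (PA14_18670, positions 1607376 to 1607852) went from 477 ± 107 to 60.8 ± 9.32 CPM, a log2 change of -2.93 (SE 0.312, adjusted p = 3.69e-09). The other large rises were those of tseT and tsiT, which encode a type VI secretion effector and its immunity protein, of pirR, of praA and of pqsH, which encodes the last enzyme of quinolone signal synthesis, with log2 changes from 1.76 (pqsH) to 2.29 (tseT). The rise of tseT was smaller in run B, with a log2 difference (run B minus run A) of -3.08 (SE 0.872, adjusted p = 0.0477 for the contrast of the runs). Large falls were found for bauA and bauB of beta-alanine catabolism, for hppD of tyrosine catabolism, for tesG and for mexG, mexH and mexI, from -2.72 (bauA) to -1.87 (bauB).

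Of the fixed gene lists, the flagellum and the phenazine lists were called between 1 and 2 h. In the flagellum list 26 of 41 genes rose and none fell (29 adjusted over the list alone), with a median log2 change of 0.44 (limma camera, adjusted p = 0.00687 with an estimated correlation). Examples were flgC (1.04, SE 0.170), fleR (0.84, SE 0.100) and flgE (0.84, SE 0.164), a rod, a regulator and the hook gene. The phenazine list was tested through 4 genes with a symbol of their own, mexG, mexH, mexI and opmD, which form an efflux pump rather than synthesise phenazines. All 4 fell (4 adjusted over the list alone), with a median of -2.02 (adjusted p = 0.00687 with an estimated correlation) and the largest change for mexH (-2.31, SE 0.209). In the quinolone signalling list 8 of 9 genes rose (9 adjusted over the list alone; median 1.45), although the list itself was not called (adjusted p = 0.0707 with an estimated correlation). After pqsH, its largest rises were pqsB (1.67, SE 0.371) and the receptor gene mvfR (1.51, SE 0.214). In the pyochelin and haem uptake list 10 of 14 rose and none fell (10 adjusted over the list alone; median 1.14), but this list was not called either (adjusted p = 0.123 with an estimated correlation). The transporter genes pchH (1.49, SE 0.203) and pchI (1.47, SE 0.186) and pchC (1.41, SE 0.282, higher in 4 of 5 cultures) led it. From the fixed panel, lasI, the gene of the las signal synthase, rose from 297.7 ± 111 to 758.7 ± 56.9 CPM (log2 1.34, SE 0.174, adjusted p = 1.21e-07) and pqsA by 1.45 (SE 0.368). The rhamnolipid gene rhlA changed by -1.02 (SE 0.149) and the ribosome hibernation gene rmf by -1.45 (SE 0.344).

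In all, 1552 genes (25.8%) differed between 2 and 1 h, 668 higher and 884 lower, of which 305 changed at least 2-fold (167 higher, 138 lower), and 1520 of the 1552 (97.9%) had the same sign in both runs. Scaling by library size alone called 1199 higher and 345 lower (77.7% higher against 43%), with the median log2 change of all genes at 0.123 in place of -0.075, so that small changes in this comparison hold relative to the TMM scale. The count dropped to 1013 without run B replicate 3, to 1012 in run B alone and to 1026 with only the 10 libraries compared, a fit in which tseT, tsiT, pqsB and pqsA were no longer called (adjusted p = 0.11, 0.145, 0.1 and 0.161). Leaving out the 1 h library of run B replicate 2, an alternative chosen after seeing the data, raised nirS from 0.67 (adjusted p = 0.571) to 3.88 (adjusted p = 0.00157) and arcD from -0.04 (adjusted p = 0.981) to 3.88 (adjusted p = 4.29e-05). It also brought the quinolone list to adjusted p = 0.00315 with an estimated correlation, and leaving out that whole culture to 0.0051. Several panel calls near the threshold were lost under other settings, lasB (-0.61, adjusted p = 0.0471) with the culture as a block (adjusted p = 0.0612) and rpoS (-0.27, adjusted p = 0.035) with no run term (adjusted p = 0.0671). The same went for pcrV (0.43, adjusted p = 0.0327) with only the libraries compared (adjusted p = 0.113) and for fliC (0.48, adjusted p = 0.0438) and rmf in run B alone (adjusted p = 0.395 and 0.0594). In run A alone the sign turned for pcrV (-0.21) and for arcD (4.34).

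The comparison of 6 h with 2 h called more genes than the other main comparisons. The elastase gene lasB (PA14_16250, positions 1387521 to 1389017) went from 40.1 ± 3.63 to 7529 ± 811 CPM (n = 5; log2 7.55, SE 0.297, adjusted p = 2.58e-25). The transcript of rmf (PA14_24650, positions 2154740 to 2154952), whose product inactivates ribosomes, went from 20 ± 5.54 to 6875 ± 1192 CPM (8.43, SE 0.440, adjusted p = 2.63e-20). The ribosomal protein gene rplL (PA14_08750, positions 745613 to 745981) went from 6223 ± 412 to 266 ± 34.4 CPM (-4.55, SE 0.180, adjusted p = 2.74e-25). Of all named genes, desB, an acyl-CoA desaturase gene (PA14_64610, positions 5755394 to 5756506), fell furthest, from 341 ± 109 to 5.28 ± 1.11 CPM (-5.96, SE 0.264, adjusted p = 5.71e-23). The remaining genes of largest rise were flp, the pilin gene of type IVb pili (8.56, SE 0.298), lasA, a second secreted protease (8.03, SE 0.398), the aminopeptidase gene paaP (7.78, SE 0.301) and phzA, phzB and phzC. These 3 phenazine synthesis genes occur in near-identical copies at 2 loci that share reads, so their changes (8.25, 8.64 and 7.89 at the copies from PA14_39970 to PA14_39945, 6.24, 5.11 and 6.47 at the other copies) are uncertain for each copy. The remaining genes of largest fall were qapR, glpD of glycerol use, loiP, lldD of lactate use, and speD, brnQ and ptsP, each of which shares its symbol with at least 1 other locus, from -5.32 (qapR) to -4.72 (ptsP).

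In most lists of growth functions the larger part of the genes was lower at 6 h than at 2 h, though none of these lists was called in the fit to all libraries. All 52 ribosomal protein genes were lower (52 adjusted over the list alone; median log2 -2.95; adjusted p = 0.102 with an estimated correlation). After rplL, rpsT (-4.51, SE 0.283) and rplJ (-4.12, SE 0.176) fell furthest. All 14 genes of RNA polymerase and translation factors were lower (14 adjusted over the list alone; median -2.55; adjusted p = 0.102 with an estimated correlation). The elongation factor gene tsf (-4.22, SE 0.161), nusG (-3.41, SE 0.126) and rho (-3.32, SE 0.151) led them. Among 16 tRNA ligase genes 15 were lower (15 adjusted over the list alone; median -1.48; adjusted p = 0.0715 with an estimated correlation). Examples were lysS (-2.85, SE 0.182), pheS (-2.63, SE 0.117) and glyQ (-2.47, SE 0.170), while metG rose (0.83, SE 0.125). This list was called without run B replicate 2 (adjusted p = 0.044) and, as alternatives chosen after seeing the data, without that culture's 1 h library (adjusted p = 0.0342) or the 10 h library of run A replicate 3 (adjusted p = 0.0357). The 5 ATP synthase genes all fell (5 adjusted over the list alone; median -2.28; adjusted p = 0.195 with an estimated correlation). The changes were -3.04 (SE 0.113) for atpB, -2.48 (SE 0.143) for atpG and -2.28 (SE 0.147) for atpD. Of 18 purine and pyrimidine synthesis genes 17 fell (18 adjusted over the list alone; median -1.85; adjusted p = 0.102 with an estimated correlation). Among them purD (-3.71, SE 0.180), purH (-3.07, SE 0.167) and pyrH (-3.05, SE 0.113) changed most. In the type III secretion list, an injection system for effector proteins, 36 of 38 genes fell and 2 rose (36 and 2 adjusted over the list alone; median -2.74; adjusted p = 0.102 with an estimated correlation). Its largest falls were those of pscD (-4.11, SE 0.166), pscY (-3.76, SE 0.277) and pscC (-3.71, SE 0.155), whereas spcU, the chaperone gene of an effector, rose (0.96, SE 0.107). Heat shock and chaperone genes fell in 12 of 15 cases and rose in 2 (12 and 2 adjusted over the list alone; median -2.22; adjusted p = 0.342 with an estimated correlation). Chaperone genes groL (-3.22, SE 0.199) and dnaJ (-3.01, SE 0.174) and the protease gene hslU (-2.67, SE 0.241) went down and clpA up (1.65, SE 0.0909).

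Lists of secreted factors and cell-to-cell signalling held mostly genes that were higher at 6 h, and 1 of these lists, type II secretion, was called. Of 12 genes of las quorum sensing and exoproteases 11 rose (11 adjusted over the list alone; median log2 4.39; adjusted p = 0.102 with an estimated correlation). The alkaline protease gene aprA (7.43, SE 0.318) rose beside lasA and lasB, and only lasI fell (-0.88, SE 0.172). In the rhl list 8 of 10 rose and 2 fell (8 and 2 adjusted over the list alone; median 4.32; adjusted p = 0.118 with an estimated correlation). The lectin gene lecA (7.39, SE 0.335), cbpD (6.96, SE 0.358) and rhlA (6.29, SE 0.175) led the list and rhlG was lower (-1.78, SE 0.278). All 9 quinolone signalling genes rose (9 adjusted over the list alone; median 2.11; adjusted p = 0.476 with an estimated correlation). Synthesis genes pqsC (2.49, SE 0.366), pqsB (2.45, SE 0.372) and pqsD (2.40, SE 0.352) were the largest. The 4 efflux pump genes of the phenazine list rose (4 adjusted over the list alone; median 6.35; adjusted p = 0.102 with an estimated correlation). For mexH the change was 6.66 (SE 0.242), for mexG 6.66 (SE 0.238) and for mexI 6.04 (SE 0.211). Type II secretion, which exports enzymes such as elastase, had 13 of 14 genes higher (13 adjusted over the list alone) and a median of 1.84, and it was the only list called in this comparison (adjusted p = 0.0491 with an estimated correlation). Of its genes, tadD (4.08, SE 0.187), xcpP (2.77, SE 0.125) and xcpT (2.36, SE 0.131) rose most and pilD fell (-0.37, SE 0.0985). The fixed list held tadD, a gene of type IVb pilus assembly. The call was lost without it (adjusted p = 0.0505, an alternative chosen after seeing the data), with library-size scaling (adjusted p = 0.13) and without run B replicate 3 (adjusted p = 0.0598). Pyoverdine genes rose in 14 of 17 cases and fell in 3 (14 and 3 adjusted over the list alone; median 1.36; adjusted p = 0.651 with an estimated correlation). The sigma factor gene pvdS changed by 5.76 (SE 0.616), pvdG by 3.33 (SE 0.531), pvdL by 2.64 (SE 0.266) and the efflux gene pvdR by -1.84 (SE 0.187). The rise of pvdS was mostly that of run B, with 12.8 and 5.97 CPM at 6 h in run A but 147 to 234 in run B. It was 1.89 in run A alone (adjusted p = 0.00198) and 7.33 in run B alone, a difference of 5.51 (SE 0.824, adjusted p = 3.86e-05) that was looked at after the data were seen. The pyoverdine list at 6 h lay at -0.996 and -0.893 in run A and at 0.308 to 0.43 in run B. Of 14 pyochelin and haem uptake genes 13 rose and none fell (13 adjusted over the list alone; median 3.09; adjusted p = 0.195 with an estimated correlation). Salicylate and pyochelin genes pchB (5.05, SE 0.308), pchC (4.76, SE 0.285) and pchA (4.64, SE 0.252) came first.

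Metabolic and stress lists were mixed at 6 h. Of 13 genes of stationary phase and general stress 12 rose and none fell (12 adjusted over the list alone; median log2 4.43; adjusted p = 0.0715 with an estimated correlation). Glycogen genes glgX (6.47, SE 0.383) and glgB (6.31, SE 0.451) were among them. The list was called without run A replicate 3 (adjusted p = 0.0203) and without that culture's 10 h library alone (adjusted p = 0.0158, an alternative chosen after seeing the data). Amino acid catabolism had 13 of 20 genes higher and 5 lower (13 and 5 adjusted over the list alone; median 2.15; adjusted p = 0.405 with an estimated correlation). Higher were mmsA of valine (5.93, SE 0.187) and hmgA (5.79, SE 0.361) and fahA (5.16, SE 0.402) of tyrosine breakdown, and putA of proline breakdown was lower (-2.47, SE 0.173). In the tricarboxylic acid cycle 7 of 10 genes fell and 3 rose (7 and 3 adjusted over the list alone; median -1.30; adjusted p = 0.51 with an estimated correlation). The fall of sucC (-2.13, SE 0.117) stood against rises of fumC (3.76, SE 0.369) and acnA (3.44, SE 0.154). Of 5 aerobic terminal oxidase genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; median -2.07; adjusted p = 0.588 with an estimated correlation). Ubiquinol oxidase genes cyoA and cyoB changed by -3.16 (SE 0.373) and -2.40 (SE 0.219) and coxB of a cytochrome c oxidase by 2.57 (SE 0.150). Of 8 oxidative stress genes 5 rose and 2 fell (5 and 2 adjusted over the list alone; median 2.00; adjusted p = 0.654 with an estimated correlation). The catalase gene katA (4.00, SE 0.399), soxR (3.74, SE 0.147) and ahpC (2.69, SE 0.388) rose and bfrB fell (-2.47, SE 0.327).

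Sulphur assimilation genes depended on the run. In the fit over both runs 10 of 12 rose between 2 and 6 h and 1 fell (10 and 1 adjusted over the list alone; median log2 2.11; adjusted p = 0.67 with an estimated correlation). Sulphonate genes ssuE (3.86, SE 0.538), ssuC (3.37, SE 0.538) and ssuB (3.32, SE 0.697) were higher and cysG lower (-0.69, SE 0.0786). At 6 h the list mean relative to all libraries was -1.44 and -1.33 in the cultures of run A but 1.5 to 2.08 in those of run B. At 5 h it lay between -1.49 and -1.01 in all 5 cultures and at 7 h between 0.986 and 1.31 in all 4. In run A alone ssuC changed by 0.17 (adjusted p = 0.734) and ssuB by -1.06 (adjusted p = 0.221), and ssuB rose in 3 of 5 cultures. The difference between the runs was itself past the threshold for cysN, a sulphate activation gene named after its value was seen, with a log2 difference (run B minus run A) of 2.91 (SE 0.296, adjusted p = 2.47e-08).

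Counts for this comparison were 4869 genes (81%), 2588 higher and 2281 lower, with 3323 changed at least 2-fold (1843 higher, 1480 lower), and 4799 of the called genes (98.6%) had the same sign in both runs. The call of ssuB was lost with only the libraries compared (adjusted p = 0.0642). Library-size scaling called 2357 higher and 2457 lower, and the median log2 change of all genes moved from 0.15 to -0.003. Camera lost most list calls once the correlation between genes was estimated, leaving 1 of the 16 called with a preset correlation.

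**Figure D2:**
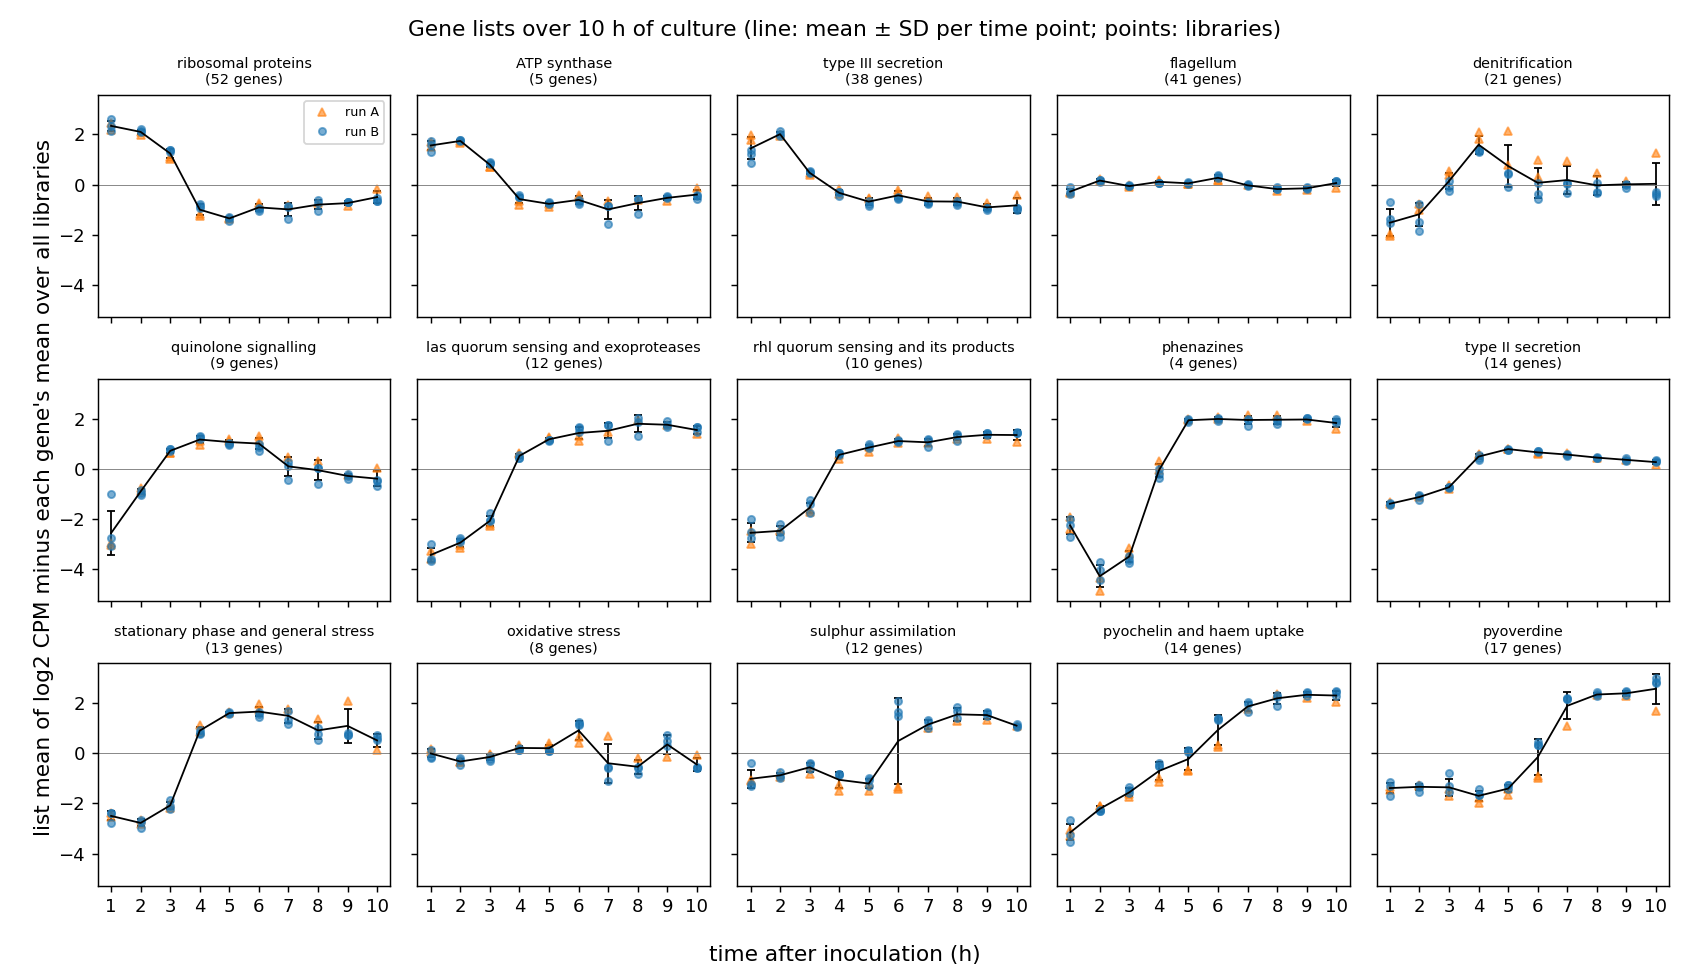
Mean log2 CPM of 15 gene lists, each gene taken relative to its own mean over the 46 libraries (y axis, log2 units), against time after inoculation (x axis, h); points are libraries (triangles run A, circles run B), the line joins time-point means and bars give the SD (n = 5 to 6 h, n = 4 from 7 h). Ribosomal protein genes lie at 2.34 at 1 h and -1.35 at 5 h, and sulphur assimilation genes at 6 h lie at -1.44 and -1.33 in run A and at 1.5 to 2.08 in run B.

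The comparison of 10 h with 6 h covered the last hours sampled. The haemophore gene hasA (PA14_20020, positions 1724698 to 1725315), whose product takes haem from host proteins, went from 3.76 ± 1.24 (n = 5) to 151 ± 52.6 CPM (n = 4), a log2 change of 5.22 (SE 0.361, adjusted p = 1.1e-14). The catalase gene katA (PA14_09150, positions 773110 to 774558) went from 1081 ± 323 to 96.6 ± 14.1 CPM (-3.49, SE 0.425, adjusted p = 3.14e-08). This was not a steady fall, with 218 ± 249 CPM at 7 h, 121 ± 51.0 at 8 h and 399 ± 214 at 9 h (n = 4). The catalase genes katE (-2.92, SE 0.480) and katB (-2.84, SE 0.384) and the alkyl hydroperoxide reductase gene ahpF (-2.95, SE 0.597) were also lower at 10 h than at 6 h. The largest falls also held dctA, a dicarboxylate transporter gene (PA14_49130, positions 4363190 to 4364500), at -3.74 (SE 0.537, adjusted p = 8.1e-07), glyA at 1 of 3 loci with that symbol (-2.80, SE 0.491), fdxH of formate dehydrogenase (-2.66, SE 0.268) and pgl of sugar phosphate oxidation (-2.55, SE 0.179). Beside hasA the largest rises were pvdQ, pvdL, pvdN, pvdO, pvdG and pvdE of pyoverdine synthesis, from 3.38 (pvdE) to 4.28 (pvdQ), and mdcE of malonate use (3.62, SE 0.241). In run A alone, which has 1 library at 10 h, the one that stands apart, dctA (-0.35, adjusted p = 0.309), ahpF (-0.47, adjusted p = 0.103), lasB (0.48, adjusted p = 0.448) and pcrV (-0.41, adjusted p = 0.123) were not called and the sign of cspD turned (-0.41 against 0.23), and the call of dctA was also lost with only the libraries compared (adjusted p = 0.052).

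Pyoverdine and type II secretion were the lists called between 6 and 10 h. Of 17 pyoverdine genes 15 rose and none fell (16 adjusted over the list alone), with a median log2 change of 2.77 (adjusted p = 0.00871 with an estimated correlation). The size of this rise differed between libraries. The list stood at 1.67 in the 10 h library of run A replicate 3 and at 2.8 to 2.99 in the other 10 h libraries. At 6 h it had been at -0.996 and -0.893 in run A and at 0.308 to 0.43 in run B. Type II secretion genes fell in 9 of 14 cases (12 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.0235 with an estimated correlation). Pseudopilin genes xcpU (-0.72, SE 0.105), xcpT (-0.69, SE 0.132) and xcpV (-0.60, SE 0.106) fell most. This call was lost with library-size scaling (adjusted p = 0.204), without run A replicate 3 (adjusted p = 0.0886) and without run B replicate 3 (adjusted p = 0.0594). Of 14 pyochelin and haem uptake genes 9 rose (9 adjusted over the list alone; median 1.00; adjusted p = 0.187 with an estimated correlation). After hasA came the receptor gene hasR (2.45, SE 0.254) and the regulator gene pchR (2.11, SE 0.180). Quinolone signalling genes fell in 6 of 9 cases (6 lower and 1 higher adjusted over the list alone; median -2.00; adjusted p = 0.297 with an estimated correlation). The largest were pqsD (-2.26, SE 0.380), pqsE (-2.26, SE 0.285) and pqsC (-2.16, SE 0.392). Of 13 stationary phase and general stress genes 9 fell and 1 rose (9 and 2 adjusted over the list alone; median -1.21; adjusted p = 0.187 with an estimated correlation). Trehalose genes treZ (-2.35, SE 0.437) and treS (-2.23, SE 0.371) fell with katE, and the sigma factor gene rpoS rose (0.71, SE 0.103). Oxidative stress genes fell in 5 of 8 cases (5 lower and 2 higher adjusted over the list alone; median -1.66; adjusted p = 0.187 with an estimated correlation). The mean of that list relative to all libraries was -0.54 at 8 h, 0.35 at 9 h and -0.45 at 10 h. Of 5 aerobic terminal oxidase genes 4 fell and 1 rose (4 and 1 adjusted over the list alone; median -1.62; adjusted p = 0.491 with an estimated correlation). The values were -1.95 (SE 0.252) for cyoB, -1.90 (SE 0.446) for cyoA and 1.74 (SE 0.148) for coxB.

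Between 6 and 10 h, 1774 genes (29.5%) differed, 843 higher and 931 lower, and 510 changed at least 2-fold (254 higher, 256 lower). The same sign was found in both runs for 1709 of them (96.3%). Library-size scaling called 618 higher and 1096 lower (36.1% higher against 47.5%), and a filter of at least 10 counts in every library, which tests fewer genes, left 296 of the 2-fold changes. Without the 10 h library of run A replicate 3, an alternative chosen after seeing the data, type II secretion was no longer called (adjusted p = 0.0688) and rmf was (log2 1.05, adjusted p = 0.0216, against 0.81 and 0.0631).

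Single steps of 1 h placed most change between 2 and 4 h. The number of genes called was 3629 for 3 h against 2 h (1693 higher, 1936 lower) and 3942 for 4 h against 3 h (2179 and 1763). It was 2480 for 5 h against 4 h (1160 and 1320), 1128 for 6 h against 5 h (668 and 460) and 1100 for 7 h against 6 h (569 and 531). It then dropped to 127 for 8 h against 7 h (35 and 92), 97 for 9 h against 8 h (48 and 49) and 164 for 10 h against 9 h (69 and 95). These last 3 counts rested on few cultures. Without run B replicate 3 they were 16, 2 and 52, without run B replicate 2 16, 4 and 56, and without run B replicate 1 the first 2 were 30 and 39. With only the libraries compared they were 28, 3 and 386, and that fit gave 669 for 7 h against 6 h. The step from 6 to 7 h also dropped to 615 without run B replicate 1 and that from 5 to 6 h to 747 without run B replicate 2. Library-size scaling shifted the balance of several steps, to 70.9% higher for 3 h against 2 h (46.7% with TMM), 45.6% for 4 h against 3 h (55.3%) and 20.2% for 5 h against 4 h (46.8%). It was 50.1% for 6 h against 5 h (59.2%). The share was also lower, at 25.8%, for 7 h against 6 h (51.7%) and at 7.38% for 8 h against 7 h (27.6%), and higher at 93.7% for 9 h against 8 h (49.5%). The median log2 change of all genes went with it, from -0.007 to 0.329 at the 3 h step and from -0.026 to -0.298 at the 5 h step. It went from 0.103 to -0.072 at the 4 h step, from 0.002 to -0.135 at the 7 h step and from -0.001 to 0.129 at the 9 h step.

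Panel genes traced the same course in single transcripts. The growth-linked regulator gene fis fell from 342 ± 45.7 CPM at 1 h to 20.7 ± 3.88 at 4 h and stood at 33.1 ± 8.63 at 6 h (n = 5; log2 6 h against 2 h -2.98, SE 0.174, adjusted p = 1.6e-19). Transcripts of rpsL, a ribosomal protein gene, and dnaA, the replication initiator gene, were also lower at 6 h than at 2 h (-2.27, SE 0.115, and -0.99, SE 0.0795). The cell division gene ftsZ stood at 756 ± 15.9 and 745 ± 77.9 CPM at 2 and 6 h (-0.03, SE 0.118, adjusted p = 0.842), with 643 ± 20.3 CPM at 3 h and a maximum of 1029 ± 85.7 at 5 h between them, and was lower at 10 h than at 6 h (-0.74, SE 0.127). The signal synthase gene lasI was highest at 2 h (758.7 ± 56.9 CPM) and pqsA at 4 h (765 ± 147 CPM), before lasB (14850 ± 2333 CPM at 10 h) and rhlA (1761 ± 70.9 CPM at 9 h; n = 4). Transcripts of rpoS rose from 203 ± 14.1 CPM at 2 h to 2551 ± 273 at 6 h (3.65, SE 0.108) and 4262 ± 788 at 10 h. Those of cspD rose from 27.8 ± 4.72 to 505 ± 67.6 at 6 h (4.17, SE 0.203) and those of hcnA of cyanide synthesis from 5.42 ± 2.82 to 66.5 ± 9.03 (3.58, SE 0.311). The flagellin gene fliC was higher at 6 h than at 2 h (1.64, SE 0.183) and the type III tip gene pcrV lower (-1.49, SE 0.154) and lower again at 10 h than at 6 h (-0.70, SE 0.164). For 2 genes used when oxygen is short, the highest mean fell in between. It was 1012 ± 547 CPM at 3 h for arcD of arginine fermentation and 239 ± 103 CPM at 4 h for the nitrite reductase gene nirS. Single cultures differed for nirS. From 3 to 4 h it rose in run A replicate 2 (260.8 to 283 CPM) and run B replicate 1 (133.8 to 182.6 CPM). It fell in run B replicates 2 (185.8 to 172.3 CPM) and 3 (231.2 to 156.2 CPM). Run A replicate 3 stood at 400.3 CPM at 4 h and 494 CPM at 5 h. Neither arcD nor nirS passed the test between 6 and 2 h (0.92, adjusted p = 0.282, and 0.75, adjusted p = 0.345).

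**Figure D3:**
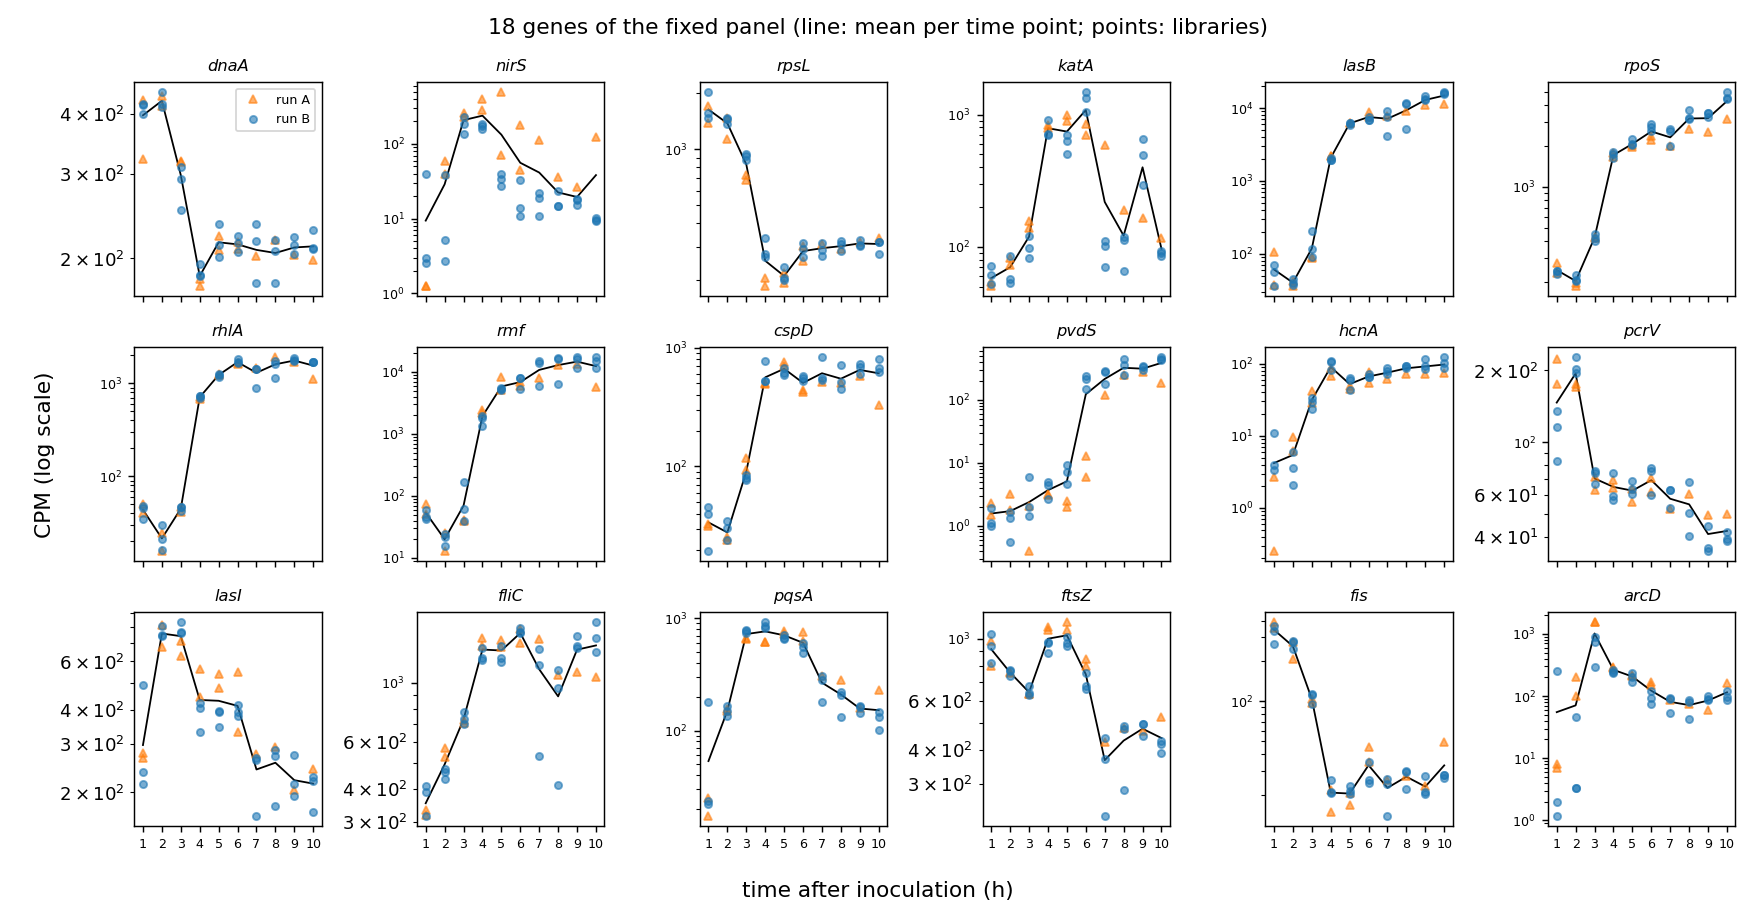
Abundance of 18 panel transcripts (y axis, CPM on a log scale, separate for each gene) against time after inoculation (x axis, h); points are libraries (triangles run A, circles run B) and the line joins time-point means (n = 5 to 6 h, n = 4 from 7 h). The lasB transcript stands at 40.1 CPM at 2 h and 14850 CPM at 10 h, and the mean of nirS is highest at 4 h (239 CPM).

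Changes differed between the runs for part of the genes, in a contrast with only 2 cultures of run A. In this contrast 977 of 6012 genes between 1 and 2 h and 1089 between 2 and 6 h had an unadjusted p below 0.05, so the called genes need not be all. A different change in run A and run B was called for 199 genes between 1 and 2 h (the signed log2 change higher in run B for 46 and lower for 153), for 352 between 2 and 6 h (251 and 101) and for 366 between 6 and 10 h (83 and 283). A lower value in run B can be a larger fall there, as for dctA and ahpF between 6 and 10 h. The last count and the values for that span rest on 1 run A library at 10 h, the one that stands apart, with its spread taken from the other groups. Of the 183 named results, 4 of 42, 11 of 95 and 7 of 46 were among these genes, for example fumC (2.86, SE 0.452), pvdG (2.93, SE 0.778), ahpC (2.02, SE 0.532) and ssuE (3.54, SE 0.626) between 2 and 6 h and dctA (-4.64, SE 0.613), ahpF (-3.42, SE 0.435), glyA (-3.09, SE 0.564) and pvdS (-3.13, SE 0.540) between 6 and 10 h. The gene PA14_09490 had the lowest adjusted p of the earliest comparison, with a log2 difference (run B minus run A) of -1.52 (SE 0.188, adjusted p = 1.02e-05). It is named here as the phenazine-modifying gene phzM, although the matching gave no locus a phzM symbol unique to it. Between 6 and 10 h, cysN (-3.70, SE 0.320, adjusted p = 4.65e-10) and oscA of sulphate starvation (-6.39, SE 0.627, adjusted p = 5.74e-08) changed the other way from the earlier span. These were named after their values were seen. The counts changed when single cultures or libraries were left out. Without run A replicate 3 those of the 2 earlier comparisons were lower. That fit leaves 1 run A library at each hour, so it cannot show whether the counts rested on that culture. The earliest was 364 without run B replicate 1 and 66 without the 1 h library of run B replicate 2.

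Expression was also set against position on the chromosome, because genes near the replication origin can be present in more copies in growing cells. The slope of relative log2 CPM on distance from dnaA, used here as the mark of the origin, was -0.345 ± 0.017 per Mb at 2 h (SD, n = 5), -0.020 ± 0.013 at 4 h and 0.158 ± 0.043 at 10 h (n = 4), with the highest mean at 7 h (0.199 ± 0.009). The difference of 0.503 per Mb between 10 h and 2 h had a two-sided exact permutation p of 0.00794, the smallest that the 126 splits of these libraries allow. The permutation exchanged libraries and not gene positions, so it does not test whether position matters. The difference was not an even gradient. The 2 most distant of 20 bins had median log2 changes of 2.27 and 2.05 between 2 and 10 h, and the other bins lay between -0.499 and 0.744. Without the 537 genes of that region (positions 2942688 to 3595940), an alternative chosen after seeing the data, 0.237 per Mb was left (47.1%, exact permutation p = 0.00794). Of the lists fixed beforehand, the region held 14 of 17 pyoverdine genes, 6 of 13 stationary phase genes, 6 of 20 amino acid catabolism genes and 3 of 10 rhl genes. In run B alone the difference was 0.535 (exact permutation p = 0.1, the smallest possible there) and with culture as a block 0.507 (exact sign-flip p = 0.125, likewise the smallest).

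**Figure D4:**
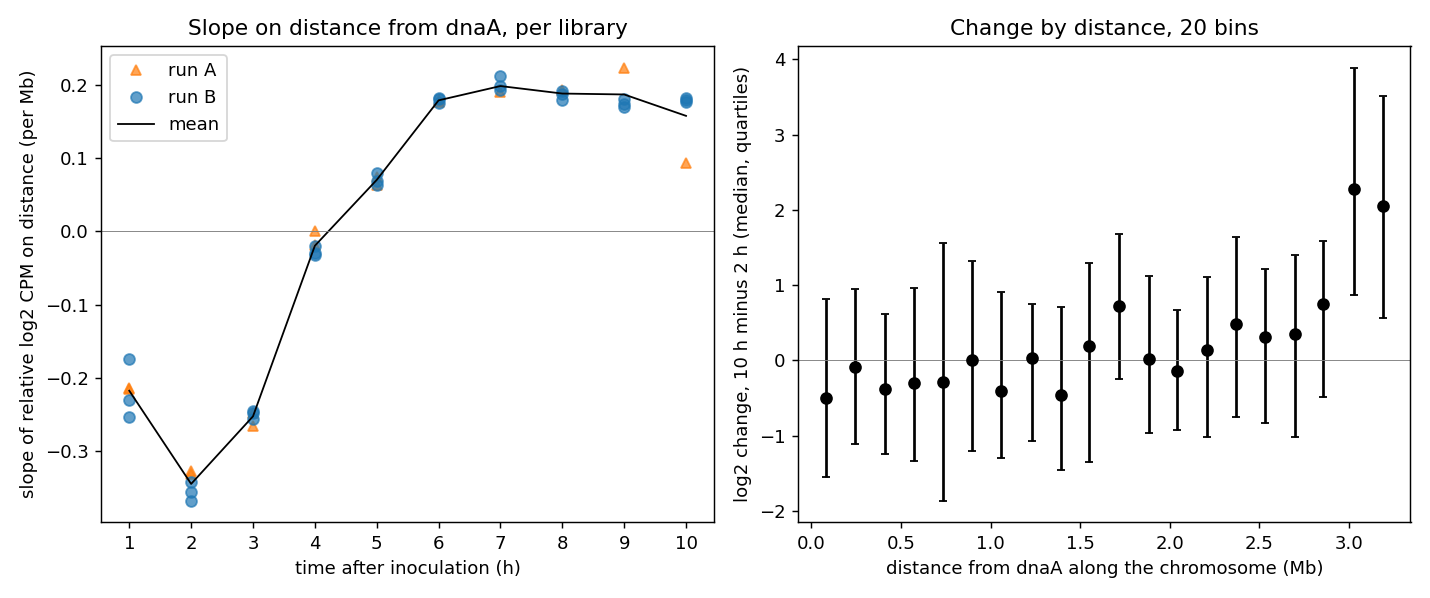
Left, slope of relative log2 CPM on distance from dnaA (y axis, per Mb) in each library against time after inoculation (x axis, h), with the line through time-point means; right, median log2 change between 2 and 10 h (y axis, with quartiles) in 20 bins of distance from dnaA (x axis, Mb). The slope goes from -0.345 at 2 h to 0.199 at 7 h, and the 2 most distant bins stand at 2.27 and 2.05.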

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

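The tests of both odd libraries, the test without the genes opposite dnaA and the change of rule for the reference point were chosen only after the results were seen. Tests of growth genes, chromosome arms and splits for gene counts were planned as run. The test of the reference position was planned with the bound of 500 kb, and the rule was then tightened to need a best point within it also without the genes opposite dnaA (272.4 kb). The scheme of the list splits was changed as well.

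The 1 h library of run B replicate 2 lay outside its group for the first principal component (-92.3, others -113.8 to -109.5), the second (-5.9), arcD (257 CPM, others 1.17 to 8.01), nirS (39.12 CPM), pqsA (179 CPM) and lasI (491.1 CPM). A share of RNA from 3 h cultures would be consistent with the 120 genes marking 3 h, which lay at a median 0.245 of their 3 h excess with 14.2% outside 2 times that fraction, and with genes specific to 3 h (0.263) against those specific to 4 h (0.022). Single 3 h libraries set against the others had 0 to 8.33% of the 120 genes outside. The 14.2% here was higher and passed only a limit of 25% set afterwards. Of the 230 genes at least 2-fold above the other 1 h libraries, 16 lay above the highest 3 h library, which such a share alone does not give. A wrong time label cannot be told apart from no error, since the nearest mean profile was that of 2 h (distance 0.58, own time 0.68) but 152 genes lay 2-fold outside the 2 h libraries, where those libraries themselves had 30 to 132, and it lay 0.85 of the 2 h range outside that range on the first component. No biological explanation was tested.

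The 10 h library of run A replicate 3 lay outside its group for the first component (31.4), the second (-21.1), the chromosome slope (0.093, others 0.177 to 0.182), nirS (124.1 CPM, others 9.27 to 10.1), rhlA (1107 CPM) and fis (49.53 CPM). A share of 3 h RNA may apply to the genes higher in it, with 20.3% of the 74 genes marking 3 h outside 2 times their median fraction of 0.192. Single 3 h libraries had 0 to 5.41% outside, so this value too passed only the limit of 25%. In addition, 32 of 161 raised genes lay above the highest 3 h library. For lower genes such a share cannot be told apart from other causes, as 321 genes marking 10 h had a median log2 difference of -0.46 where mixing allows -0.31. A lasting difference of the culture is excluded for the first component by the gap at 9 h (-5.2, against 18.9 at 10 h) but stays open for the denitrification genes, whose list lay above the run B mean by 1.03, 0.64, 0.16 and 1.66 at 7, 8, 9 and 10 h. A wrong time label cannot be told apart from no error. In a test added last, the library lay at least 1.9 ranges outside every other time point on the first 2 components. It lay 8.43 outside its own, however, so these components do not favour the label. Its ribosomal list (-0.167) lay outside the range of each other hour, but its denitrification list (1.274) lay within that of 5 h (-0.092 to 2.123). The nearest profile was that of 9 h (0.55 against 0.58 to its own time), and 180 genes lay 2-fold outside the 9 h libraries, within their own 11 to 186. No biological explanation was tested.

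The slope of expression on distance from dnaA differed between 10 h and 2 h by 0.503 per Mb. The 144 listed growth, rRNA and tRNA genes are excluded as the main cause, as 0.482 was left without them. Other genes that change with growth were not removed, so the test does not cover them. A region on 1 arm alone is excluded by the lower of the arms at 0.429. The genes opposite dnaA lie on both arms, however, and were kept in that test. The largest difference was found for a reference point 181.6 kb from dnaA, within the bound of 500 kb, which speaks against an arbitrary position, but this scan separates little, because a block of genes opposite dnaA alone gives a best point near dnaA. A difference of 0.237 was left without the genes opposite dnaA, which carried over 50% of the whole. An exchange of libraries cannot show whether this remainder depends on position, as gene positions were not permuted. A change in gene copy number with growth is a hypothesis that might apply to the remainder, and no value here separates it from regulation of genes by position.

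Chance can be excluded for the gene counts of the main comparisons, where 1 split of 100, the real one, was as large (real and highest other 1026 and 120 for 2 h against 1 h, 4698 and 0 for 6 h against 2 h, 1855 and 827 for 10 h against 6 h), and for their 2-fold counts (188 and 66, 3272 and 0, 492 and 275). The same holds for the steps to 3 h (3773 and 0), 4 h (4285 and 0), 5 h (3081 and 0) and 6 h (1452 and 9), for that to 10 h (386 and 89, of 35 splits) and for any time point (5728 and 1621). At the step to 7 h the real split was the largest tried (669). Another reached 652 and not all splits were run, so chance is not excluded there. Except for any time point, these counts came from fits to the compared libraries alone and differ from those of the full fit. At the step to 9 h the real split was also the largest of 35 (3 and 0), but 3 genes, from a fit to those libraries alone, decide nothing about the 97 called in the full fit. For 8 h against 7 h chance was not excluded, as 2 of 35 splits were as large (real 28, highest 1143), and the larger one set run A replicate 3 and run B replicate 1 against run B replicates 2 and 3, a structure of the samples. For gene lists called, 7 of 100 splits were as large between 2 and 6 h (real 1, highest 1). It was 2 of 100 between 1 and 2 h (real 2, highest 3) and 1 of 100 between 6 and 10 h (real 2, highest 1), the real split included. The list counts used an exchange of labels within the full fit, chosen after a fit to the compared libraries alone had called no list in the real split. They therefore do not exclude chance for the lists.

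Of 260 groups of 4 or 5 libraries over 26 measures, 34 held a library outside by Dixon's criterion, where chance gives about 1 in 20, or 13. Run A replicate 3 stood out for nirS at 5 h (494 CPM), 6 h (177.6 CPM) and 7 h (114.1 CPM), katA at 7 h (591.3 CPM), ssrA at 9 h (23.11%), the second component at 9 h (-24.6), rpoS at 1 h (276.2 CPM) and rRNA at 5 h (1.173%). Run A replicate 2 stood out for ssrA (17.13%) and dnaA (323 CPM) at 1 h and rmf at 5 h (8272 CPM). Run B replicate 1 stood out for lasB (203.1 CPM) and rmf (168.1 CPM) at 3 h, cspD at 4 h (765.8 CPM), rhlA (890.1 CPM), lasI (164 CPM) and fis (13.78 CPM) at 7 h and ftsZ at 8 h (287.6 CPM). Run B replicate 2 stood out for lasB at 5 h (5897 CPM), rhlA at 6 h (1829 CPM) and cspD at 7 h (834.8 CPM), and run B replicate 3 for ftsZ at 3 h (678.5 CPM). A different change in the 2 runs was called, by a contrast of the 2 runs' changes, for 199, 352 and 366 genes in the 3 main comparisons, the last with 1 run A library at 10 h, the one that stands apart.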

How the results depend on the processing

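Leaving out the 1 h library of run B replicate 2, the 10 h library of run A replicate 3, the genes opposite dnaA or tadD were tests chosen only after the results were seen, and all other alternatives were planned. The cause of a changed count was not tested.

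With at least 10 counts in every library, 2-fold counts were 188 (2 h against 1 h) and 296 (10 h against 6 h). DESeq2 gave 165 genes at the 9 h step and 316 run differences between 1 and 2 h. Without the run term the 8 h and 9 h steps gave 80 and 62 genes and the lists between 2 and 6 h were 2. Run B alone gave 1012 genes for 2 h against 1 h and 746 at the 6 h step. Run A alone gave 496 2-fold changes for 2 h against 1 h and 1544, 726, 348, 80 and 674 genes at the 5, 6, 7, 8 and 10 h steps, where it has 1 library at each hour from 7 h on, so that the spread comes from the earlier hours. With only the libraries compared, 2 h against 1 h gave 1026 genes (188 2-fold) and the 7, 8, 9 and 10 h steps gave 669, 28, 3 and 386.

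Lists called were 10, 16 and 13 with the preset correlation and 15, 30 and 19 with fry, against 2, 1 and 2. The fry test asks whether a list changes at all, whereas camera sets it against the other genes. The fry counts therefore answer another question, and a high count follows where most genes change. Library size alone gave 0 lists between 2 and 6 h and 1 between 6 and 10 h. Without the 1 h library of run B replicate 2, lists between 2 and 6 h were 3 and run differences between 1 and 2 h 66. Without the 10 h library of run A replicate 3, lists were 4 between 2 and 6 h and 1 between 6 and 10 h.

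Leaving out each culture gave 1013 to 1527 genes for 2 h against 1 h (258 to 414 2-fold, 2 to 4 lists, 9 to 364 run differences), 4682 to 4777 for 6 h against 2 h (3296 to 3332, 0 to 3 lists, 115 to 358) and 1332 to 1678 for 10 h against 6 h (507 to 517, 1 to 3 lists, 240 to 451). Hourly steps gave 3259 to 3548 (3 h), 3671 to 3801 (4 h), 2028 to 2308 (5 h), 747 to 1022 (6 h), 615 to 1100 (7 h), 16 to 153 (8 h), 2 to 89 (9 h) and 52 to 165 (10 h), and any time point 5602 to 5663. Counts moved over 1.5-fold without run B replicate 3 (1013, 16, 2, 52), run B replicate 2 (747, 16, 4, 56 and run differences 19, 198, 240), run B replicate 1 (615, 30, 39, 364), run A replicate 3 (9, 115) and run A replicate 2 (194). The run difference between 6 and 10 h without run A replicate 3 was not run, as run A then has no 10 h library.

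Library size alone in place of TMM gave as higher and lower genes 1199 and 345 (668 and 884 with TMM) for 2 h against 1 h, 2357 and 2457 (2588 and 2281) for 6 h against 2 h, 2605 and 1069 (1693 and 1936) at the 3 h step, 1767 and 2104 (2179 and 1763) at 4 h, 612 and 2416 (1160 and 1320) at 5 h, 489 and 488 (668 and 460) at 6 h, 323 and 930 (569 and 531) at 7 h, 11 and 138 (35 and 92) at 8 h, 89 and 6 (48 and 49) at 9 h, 46 and 78 (69 and 95) at 10 h and 618 and 1096 (843 and 931) for 10 h against 6 h.

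Culture as a block changed no count over 1.5-fold. It ended the call of lasB for 2 h against 1 h (-0.59, adjusted p = 0.0612), left 182 of 183 named results and 95 of 96 list results as they were and called type II secretion between 1 and 2 h (adjusted p = 0.041), as did RLE factors (0.0267) and leaving out run A replicate 2 (0.0348) or run B replicate 1 (0.0382). Without tadD in the type II secretion list, 0 lists were called between 2 and 6 h (type II secretion at adjusted p = 0.0505). The slope difference was 0.507 with culture as a block (p = 0.125), 0.535 in run B alone (p = 0.1) and 0.491 to 0.53 without each culture (exact permutation p = 0.0286), and 0.487 to 0.589 under the other planned settings.

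The sign turned for pcrV (-0.21) and arcD (PA14_68300, 4.34) between 1 and 2 h, ssuB (-1.06) between 2 and 6 h and cspD (-0.41, with 1 library at 10 h) between 6 and 10 h in run A alone, and for arcD also without the 1 h library of run B replicate 2 (3.88) and without run B replicate 2 (4.18; range without each culture -1.22 to 4.18). Of 3063 alternative values for named genes, 2988 were the same, 46 weaker, 23 stronger and 6 reversed. Of 1251 for lists, 1132 were the same, 7 weaker, 112 stronger and 0 reversed. Small changes were found in part, with 40.3 to 52.2% of planted log2 changes of 0.5 recovered; depth alone was not varied.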

Other observations

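The lists and genes of this part were looked at only after the results were seen, apart from the list tests themselves, which were planned. The lists for growth without oxygen had their highest mean in mid course. The denitrification list, for respiration on nitrate, stood at -1.52 at 1 h and 1.59 ± 0.358 at 4 h and the low-oxygen list at -1.94 and 1.12 ± 0.053 (relative log2, SD, n = 5), at an hour that the main comparisons pass over. The denitrification list was also high in the libraries that stand apart, at -0.70 in the 1 h library of run B replicate 2 (others -2.05 to -1.37) and at 1.27 in the 10 h library of run A replicate 3 (others -0.46 to -0.31). So was the low-oxygen list, at -0.64 in that 1 h library (others -2.59 to -2) and at 0.52 in that 10 h library (others 0 to 0.15). Neither list was called between 2 and 6 h (10 of 21 denitrification genes higher and 2 lower, 10 and 1 adjusted over the list alone, adjusted p = 0.643 with an estimated correlation; 6 of 11 low-oxygen genes higher and 1 lower, 6 and 1 adjusted over the list alone, adjusted p = 0.47 with an estimated correlation). Between 1 and 2 h, 3 denitrification genes were lower (3 adjusted over the list alone), with a median of -0.14 and a mean of 0.05, and the test pointed up (adjusted p = 0.714 with an estimated correlation), while 4 low-oxygen genes were higher and 3 lower (4 and 3 adjusted over the list alone; adjusted p = 0.675 with an estimated correlation). Between 6 and 10 h, 3 denitrification genes were higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.889 with an estimated correlation) and 2 low-oxygen genes were lower (2 adjusted over the list alone; adjusted p = 0.611 with an estimated correlation).

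Surface and secretion lists outside the described ones moved in part. In the type III secretion list 23 of 38 genes rose between 1 and 2 h (26 adjusted over the list alone; median 0.58; adjusted p = 0.123 with an estimated correlation, 0.0371 without run A replicate 2) and 12 fell between 6 and 10 h (13 adjusted over the list alone; adjusted p = 0.442 with an estimated correlation). The flagellum list had 15 of 41 genes higher and 10 lower between 2 and 6 h (15 and 10 adjusted over the list alone; adjusted p = 0.851 with an estimated correlation) and 9 lower between 6 and 10 h (9 adjusted over the list alone; adjusted p = 0.297 with an estimated correlation). Of 18 type IV pilus genes, 6 rose and 3 fell between 1 and 2 h (6 and 5 adjusted over the list alone; adjusted p = 0.699 with an estimated correlation), 5 rose and 9 fell between 2 and 6 h (5 and 9 adjusted over the list alone; adjusted p = 0.651 with an estimated correlation) and 9 fell between 6 and 10 h (11 lower and 1 higher adjusted over the list alone; adjusted p = 0.187 with an estimated correlation). Of 10 type VI secretion genes, 2 rose between 1 and 2 h (2 adjusted over the list alone; adjusted p = 0.415 with an estimated correlation), 2 rose and 4 fell between 2 and 6 h (2 and 4 adjusted over the list alone; adjusted p = 0.654 with an estimated correlation) and none was called later (0 adjusted over the list alone; adjusted p = 0.889 with an estimated correlation). Of 12 pel and alginate genes, 3 rose and 3 fell between 2 and 6 h, where the median (0.71) and the direction of the test (down) disagreed (0 higher and 3 lower adjusted over the list alone; adjusted p = 0.872 with an estimated correlation).

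Growth and repair lists were mixed after 6 h, and none was called. Of 52 ribosomal protein genes 26 rose between 6 and 10 h (27 adjusted over the list alone; median 0.39; adjusted p = 0.446 with an estimated correlation). The ribosomal list stood at -0.17 in the 10 h library of run A replicate 3 and at -0.65 to -0.54 in the other 10 h libraries. Of 15 heat shock genes 8 rose and 1 fell (8 and 2 adjusted over the list alone; adjusted p = 0.401 with an estimated correlation). All 9 NADH dehydrogenase genes, of the respiratory complex I, fell in that span (9 adjusted over the list alone; median -0.82; adjusted p = 0.187 with an estimated correlation) and all 4 spermidine genes rose (4 adjusted over the list alone; median 0.38; adjusted p = 0.187 with an estimated correlation). The NADH dehydrogenase list was called without run B replicate 1 (adjusted p = 0.0194). Between 2 and 6 h 3 of its 9 genes were lower (2 adjusted over the list alone; median -0.18; adjusted p = 0.758 with an estimated correlation). Of 24 replication and division genes 21 fell and 1 rose between 2 and 6 h (21 and 1 adjusted over the list alone; median -0.85; adjusted p = 0.0505 with an estimated correlation), a list called with no run term (adjusted p = 0.0354), without run A replicate 3 (0.0203), without run B replicate 2 (0.0405) and without either library that stands apart (0.0342 and 0.0158). In the SOS list, for repair of damaged DNA, 7 of 13 genes fell between 1 and 2 h (7 adjusted over the list alone; adjusted p = 0.0978 with an estimated correlation, 0.0382 without run B replicate 1) and 10 fell and 3 rose between 2 and 6 h (10 and 3 adjusted over the list alone; adjusted p = 0.184 with an estimated correlation). Phosphate genes fell in 7 of 10 cases and rose in 2 between 2 and 6 h (7 and 2 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation), and zinc genes fell in 5 of 9 (4 adjusted over the list alone; adjusted p = 0.264 with an estimated correlation). Median and test pointed to opposite sides for pyoverdine, rhl and oxidative stress genes between 1 and 2 h, and mean and median differed in sign for sulphur, amino acid catabolism and tRNA ligase genes between 6 and 10 h. None of these lists was called there.

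Phenazine synthesis genes could not be assigned to a locus in full. The 12 copies of phzA to phzF changed by 5.11 to 8.64 between 2 and 6 h and by -2.04 to -0.89 between 6 and 10 h, with reads shared between the copies. The share of such reads was not measured. It was not complete for phzB, whose copies changed by 8.64 (SE 0.43) and 5.11 (SE 0.381) between 2 and 6 h.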
